A study of Mus musculus with 4 samples.

How the data were processed

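Chromatin immunoprecipitation with sequencing (ChIP-seq) was measured in primary mouse CD4+ conventional T cells. The labels describe 4 samples with 1 library each. FLAG-tagged FoxP3 was precipitated with an anti-FLAG antibody from cells that had received FLAG-FoxP3 together with GATA1, and from cells that had received FLAG-FoxP3 alone. RNA polymerase II (Pol II) was precipitated from a culture whose title and transduced-factor label name FoxP3 and GATA1, while its description mentions activated CD4 cells and no transduced factor. A whole cell extract was the sequencing control, labelled as having no transduced factor. Its own reads were not analysed here. Each sample is its own group, so there were no replicates and no test across samples.

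Per the submitters' processing notes, FastQC, Bowtie and MACS 1.4.0rc2 were used and the genome build was mm8. The notes give no role, order or setting for these tools. The Bowtie version, read filters and score threshold are not given in the sources used here. The authors deposited 1 peak list per precipitated library, called separately and not on pooled samples. By the naming of the lists, each ChIP lane was called over the same extract lane, so all 3 lists share that control. Each list holds the chromosome, start, end and name of a peak and a deposited score. In the usual layout of that caller's peak files the score is 10 times the negative log10 of the peak's p-value. Many of the highest peaks tie at 3100, while 2 peaks of the FoxP3+GATA1 list score above it. What the tied value stands for is not given in the sources used here. The 2 peaks above it are therefore not shown to be stronger than the tied ones. The lowest deposited score was 70.56 with FoxP3 and GATA1, 70.75 with FoxP3 alone and 50.02 for Pol II. The score depends on the read depth of the ChIP library and the extract. It was therefore used to describe, rank and filter peaks within a list. Setting both FoxP3 lists at a common minimum score does not put them on one scale. The lists hold no read counts, so the depth of each library is unknown and no interval that needs it is given.

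Positions are printed with a first base of 1, so 1 was added to each start that the lists give, and ends are as given. They were not converted between builds. The build is uncertain. The furthest peak on chromosome 7 ended at 152430305, which lies past the end of that chromosome in the mm8 assembly as generally known. On 8 of 21 chromosomes the furthest peak also lay past the last gene of the GRCm38.p6 gene table, so that table was not used to name genes or positions. No genome or annotation of the build of the lists was used. The planned comparisons with annotated start sites, fixed gene lists and sequence motifs were therefore not run, and regions are identified by position only. Pol II peaks served as the marker of transcribed start sites that the design names.

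Peaks of different lists were counted as overlapping when they shared at least 1 bp. Counts were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and were checked against bedtools 2.31.1, which gave equal numbers for all pairs of lists. Shares carry Wilson 95% intervals, and medians carry 95% order-statistic intervals. These cover counting error over peaks only, not the variation between cultures. Overlap by chance was estimated from 1000 random placements of a list, each peak staying on its chromosome between the first and last peak of any list. Random placement ignores unmappable sequence, so a second set moved each peak by 1 to 2 Mb in either direction. Peaks separated by gaps of at most 12.5 kb were joined into clusters, and clusters of 4 or more peaks were counted against 100 placements. Peaks scoring 3000 or more, of any list, were joined into regions across gaps of up to 300 kb. The overlap code was tested on simulated data: with 20%, 50% or 80% of a FoxP3 list planted on Pol II peaks, 100% of the overlaps present were recovered in both lists of 9011 and 5069 peaks.

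Before the data were examined, the groups, the overlap definition, the alternatives and the rule for named regions were fixed. The rule names the 10 highest-scoring peaks in both FoxP3 lists, ordered by the lower of the 2 ranks, read as the worse standing, and the 10 highest-scoring peaks of each single list. It also names the 5 widest peaks of each list and the 5 regions with the most peaks. Where more than 10 shared peaks tied at 3100 in both lists, the tied peaks are described by region. Alternatives varied the overlap definition, the minimum score, the list length, the merging of peaks and chromosome X. Chosen after the data were seen were the minimum scores of 150 and above, removal of peaks of 450 bp or less, removal of peaks scoring 3000 or more, the 1000 highest-scoring peaks of each list, and the shifted placement. The score of 3000 and the gap of 300 kb that define the joined regions were not fixed beforehand either.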

Results

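The genome-wide positions of FoxP3, the transcription factor that marks regulatory T cells, were compared between CD4+ conventional T cells carrying FLAG-FoxP3 with GATA1 and cells carrying FLAG-FoxP3 alone. GATA1 is a zinc-finger transcription factor known chiefly from red blood cell development. The cells came from lymph nodes of C57BL/6 mice and had been activated through CD3 and CD28. The anti-FLAG list of the FoxP3 and GATA1 culture held 9011 peaks, and the list of the FoxP3 alone culture held 5069. A Pol II list of 17632 peaks marked transcribed regions. There was 1 library per group, the read depth is unknown, and no difference between lists has a replicate check.

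The comparison of the FoxP3 lists addressed whether the cofactor changed where FoxP3 was found. FoxP3 peaks were 1.78 times as numerous with GATA1 as without it. They covered 5.61 Mb with GATA1 and 2.88 Mb without. Median peak width was 589 bp with GATA1 (quartiles 530 and 698) and 560 bp without (quartiles 463 and 620). Scores ran the other way: the median was 195.2 (quartiles 153.5 and 269.4) with GATA1 and 425.5 (quartiles 351.3 and 541.6) for FoxP3 alone. At a minimum score of 150, 6990 peaks with GATA1 stood against 5006 without. At 200 the order reversed, with 4272 against 4971 peaks, and at 300 there were 1770 against 4536. The direction of the difference in number therefore held only at common minimum scores of 150 and below among those examined.

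**Figure D1:**
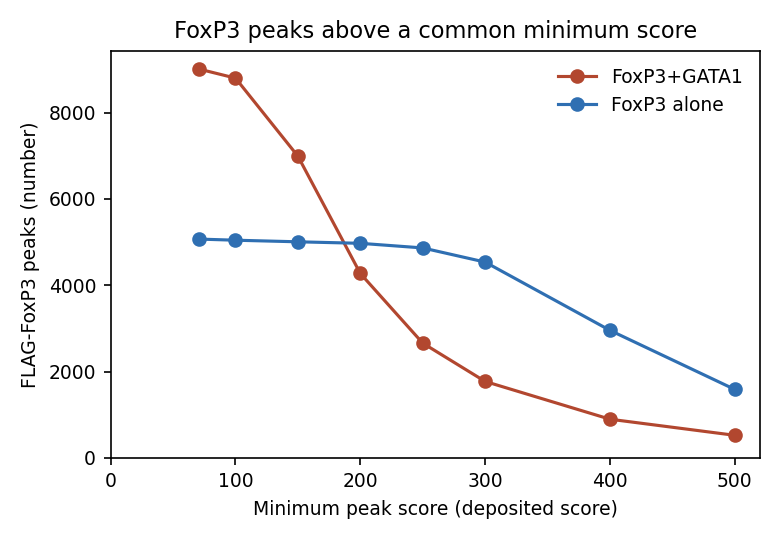
Number of FLAG-FoxP3 peaks (vertical axis) at or above a common minimum deposited score (horizontal axis) in the FoxP3+GATA1 list and the FoxP3 alone list, 1 library each. The FoxP3+GATA1 list is longer up to a score of 150 and shorter from 200 on.

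Most sites found with FoxP3 alone were found again with GATA1, while most sites found with GATA1 were in that list only. Of the 5069 FoxP3 alone peaks, 3174 overlapped a peak of the FoxP3 and GATA1 list, or 62.6% (95% interval 61.3 to 63.9). Of the 9011 peaks with GATA1, 3171 overlapped a FoxP3 alone peak, or 35.2% (34.2 to 36.2). Random placement gave means of 0.424% and 0.243%, and no placement passed 0.769%. The 2 lists thus left 5840 peaks found only with GATA1 and 1895 found only without it. All lists were called against the same extract, so part of the overlap may come from that shared control. No anti-FLAG precipitation from cells without FLAG-FoxP3 was among the samples. Peaks from non-specific precipitation are therefore not told apart from FoxP3 sites. When the list with GATA1 was reduced to its 5069 highest-scoring peaks, 46.6% of them were shared, as were 46.7% of the FoxP3 alone peaks.

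Sharing followed the score rank within each list. In the decile of the FoxP3 and GATA1 list with the highest scores, 76.1% of peaks (73.2 to 78.8) were in the FoxP3 alone list, against 18.4% (16.0 to 21.1) in the lowest decile. In the FoxP3 alone list, 95.1% (92.8 to 96.6) of the top decile was in the other list. The lowest share there was 41.4% (37.2 to 45.8), in the third decile from the bottom, and the lowest decile had 53.3% (48.9 to 57.6). Shared peaks had a median score of 254.9 within the list with GATA1, against 177.9 for peaks of that list only. Within the FoxP3 alone list the medians were 464.2 and 376.8.

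**Figure D2:**
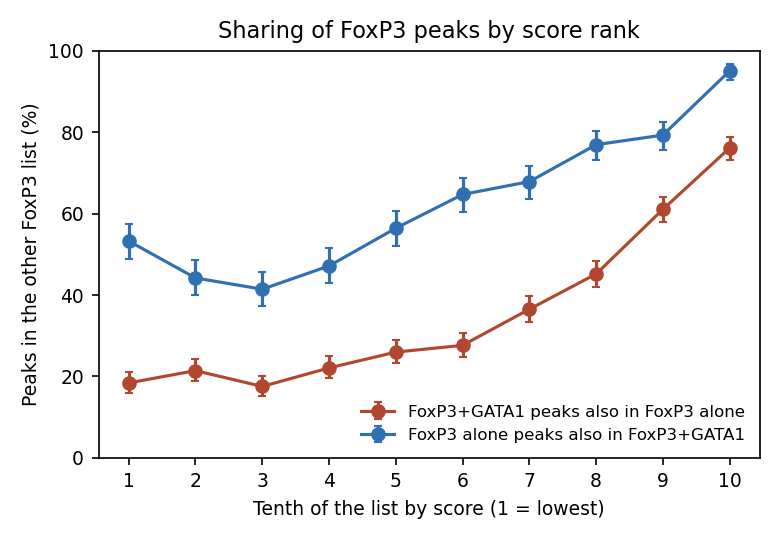
Percent of FoxP3 peaks that overlap a peak of the other FoxP3 list (vertical axis) in each decile of a list by score (horizontal axis, 1 is the lowest), with Wilson 95% intervals as error bars. The share reaches 76.1% in the top decile of the FoxP3+GATA1 list and 95.1% in that of the FoxP3 alone list.

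The highest-scoring peaks shared by the FoxP3 lists lay in part in groups on chromosomes 1, 15 and X and in part singly. Positions here are in the genome build of the peak lists, which is uncertain. The submitters' processing notes name mm8, but the furthest peak on chromosome 7 ended past the end of that chromosome in mm8. On chromosome 1, between 170087902 and 170362034, each of the 3 lists, Pol II included, held 8 separate peaks with a score of 3100, joined here across gaps of up to 300 kb. With GATA1, 6 of them lay between 170087955 and 170139980 and the other 2 between 170357693 and 170361944. On chromosome 15, between 103143932 and 103165317, there were 4 such peaks with GATA1, 5 with FoxP3 alone and 5 for Pol II. On chromosome X, between 7162957 and 7170649, there were 3, 3 and 4. The peaks at 69584918 to 69586461 on chromosome 1, 5905804 to 5907018 on chromosome 11 and 43853653 to 43856085 on chromosome 9 also reached 3100 in all 3 lists. Sites at 40582675 to 40583853 on chromosome 19 and 63796648 to 63798056 on chromosome 8 reached 3100 in both FoxP3 lists only. Those at 32161811 to 32164484 and 35112387 to 35113401 on chromosome 9 did the same. Of these FoxP3+GATA1 peaks, only the one at 32161811 overlapped no Pol II peak. The others overlapped a Pol II peak of lower score. The region at 98502208 to 98507667 on chromosome 2 also held a peak of 3100 in each FoxP3 list, and no Pol II peak of 3100. The one with GATA1 overlapped a FoxP3 alone peak with a score of 2062 and a Pol II peak of lower score. Of the peaks scoring 3000 or more, 30 of 32 with GATA1, 23 of 25 with FoxP3 alone and 21 of 24 for Pol II overlapped peaks of both other lists. Scores above 3100 were held by 2 peaks with GATA1, at 100188121 to 100188795 on chromosome 12 (3233) and 166267041 to 166267921 on chromosome 2 (3113), named after their values were seen. They overlapped FoxP3 alone peaks with scores of 1699 and 2089. The genes at these positions were not analysed here, nor whether any of the regions with a score of 3100 in all 3 lists, the one on chromosome 9 included, holds sequence of a transduced construct.

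**Figure D3:**
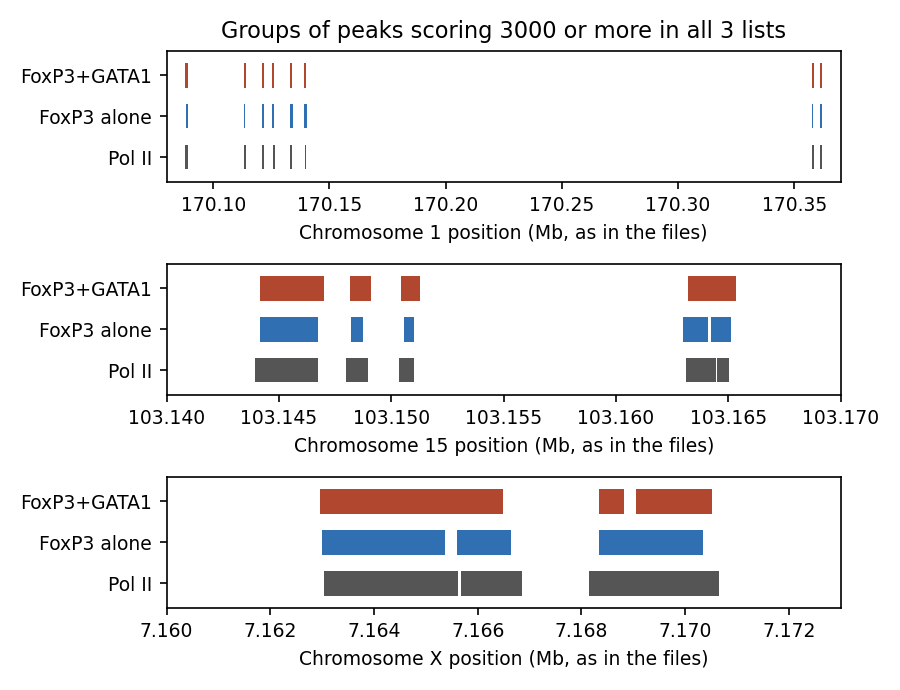
Positions of peaks with a score of 3000 or more in the FoxP3+GATA1, FoxP3 alone and Pol II lists. The 3 regions are on the horizontal axes, in Mb of the build of the lists. Each bar is 1 peak drawn to scale. The Pol II peaks ending at 7169111 and starting at 7169116 on chromosome X are too close to be seen apart. The groups on chromosomes 1, 15 and X are present in all 3 lists.

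Sites found only with GATA1 began lower in the ranking than the shared ones. The strongest, at 4706791 to 4707847 on chromosome 7, scored 2205 and ranked 40 in its list. It was followed by 6104701 to 6105161 on chromosome 10 (score 1329), 51945394 to 51946057 on chromosome 2 (score 1161) and 100520596 to 100521766 on chromosome 6 (score 1126). None of these 4 overlapped a Pol II peak. The next were 54911901 to 54912405 on chromosome 14 (score 1083) and 87649691 to 87650303 on chromosome 8 (score 1061), which both did. The remaining 4 of the 10 lay on chromosome 8 at 59762886 to 59763303, on chromosome 4 at 144485313 to 144486095 and 58592167 to 58593085, and on chromosome 11 at 79604361 to 79605492. Their scores ran from 973.9 to 1045, and none overlapped a Pol II peak, which left 2 of the 10 with one.

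Among sites found only with FoxP3 alone, 7 of the 10 strongest overlapped a Pol II peak. The strongest was a 1808 bp peak at 4995054 to 4996861 on chromosome 17 with a score of 2050 and rank 43 in its list. The peaks at 116549549 to 116550854 on chromosome 4 (score 1202), 84652087 to 84652308 on chromosome 10 (score 1043) and 43624945 to 43626143 on chromosome 5 (score 1019) also had one. So did those at 134516294 to 134517289 on chromosome 6 (score 977.0), 75473009 to 75474130 on chromosome 9 (score 962.3) and 18167623 to 18168131 on chromosome 14 (score 921.2). The 3 without one lay at 2361363 to 2361768 on chromosome Y (score 1307), and at 115922074 to 115922818 and 67678330 to 67679559 on chromosome 9 (scores 1023 and 1022). Presence in a single list does not show a difference in occupancy, since the other library can fall just under its threshold at the same site.

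The Pol II list was used to ask how many FoxP3 sites lay at transcribed start sites. A Pol II peak overlapped 49.7% (48.7 to 50.7) of FoxP3 peaks with GATA1 and 67.5% (66.2 to 68.7) of those with FoxP3 alone. Random placement gave 0.941% and 0.902%. The share was 17.8 percentage points higher for FoxP3 alone (95% interval 16.1 to 19.4). At equal list length, with the 5069 highest-scoring peaks with GATA1, the difference was 9.09 points (7.22 to 10.96). The median distance between the centres of a FoxP3 peak and the nearest Pol II peak was 849 bp (471 to 1843) with GATA1 and 151 bp (144 to 158) without. With peaks of score 100 or more in all lists these medians were 13684 and 203 bp, and from edge to edge 210 and 0 bp. The wide interval of the first reflects that close to 50% of its peaks lay within 1 kb of a Pol II peak. Random placement gave mean medians of 81412 and 81559 bp. The Pol II culture was labelled as carrying GATA1, so it matched the FoxP3 and GATA1 culture by label and not the FoxP3 alone culture.

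Sites common to both FoxP3 lists overlapped Pol II most often. Of the 3171 shared peaks of the list with GATA1, 2529 had a Pol II peak, or 79.8% (78.3 to 81.1). Of the 5840 peaks found only with GATA1, 1949 did, or 33.4% (32.2 to 34.6). Of the 1895 found only with FoxP3 alone, 888 did, or 46.9% (44.6 to 49.1). The 3 intervals did not overlap one another. Pol II overlap also differed by score. With GATA1 it was 35.0% in the lowest score decile and 72.7% in the highest. With FoxP3 alone it was 56.4% and 89.7%. Shared peaks had the higher median score in each FoxP3 list, so being shared and scoring high were not separated here. Without a Pol II peak were 3891 sites found only with GATA1, 1007 found only with FoxP3 alone and 642 shared sites. Seen from the Pol II list, 25.5% (24.9 to 26.1) of its peaks overlapped a FoxP3 peak with GATA1 and 19.5% (18.9 to 20.1) a FoxP3 alone peak, while 69.5% (68.8 to 70.1) overlapped neither. Pol II peaks shared with both FoxP3 lists had a median score of 188.8, against 107.0 for those in neither. In the decile of highest Pol II scores, 56.8% (54.5 to 59.1) overlapped a FoxP3 peak with GATA1 and 53.4% (51.0 to 55.7) a FoxP3 alone peak.

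**Figure D4:**
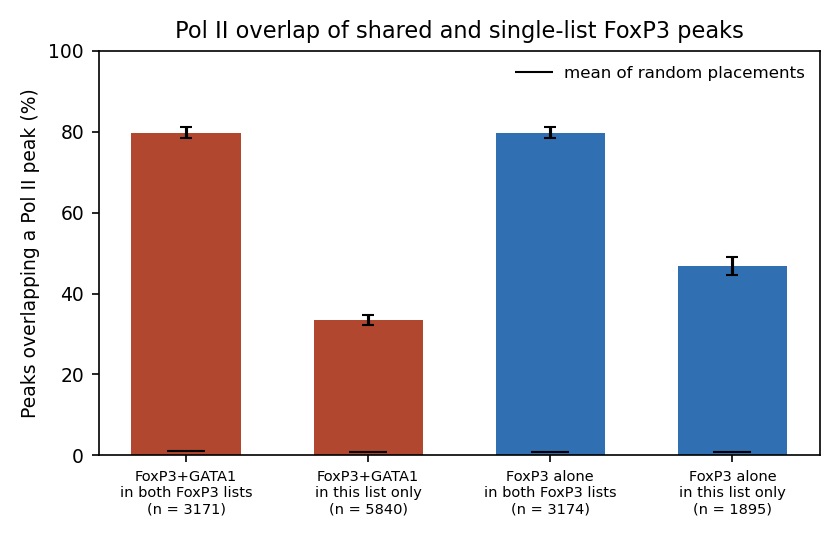
Percent of FoxP3 peaks overlapping a Pol II peak (vertical axis) for peaks in both FoxP3 lists or in this list only; error bars are Wilson 95% intervals and black dashes the mean of 1000 random placements. Shared peaks reach 79.8%, against 33.4% and 46.9% for peaks of a single list.

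Clusters of closely spaced peaks were counted in each list against random placement. With GATA1 there were 10 clusters of 4 or more FoxP3 peaks, against a mean of 0.66 for random placement, and with FoxP3 alone there were 5, against 0.12. The Pol II list held 308, against 15.5. These counts rest on the largest gap allowed within a cluster: at 5 kb they were 1, 1 and 101, against means of 0.03, 0 and 1.49, and at 50 kb 102, 26 and 1058, against 38.1, 4.43 and 396.2. At 5 kb the count of 1 with GATA1 was also reached by random placement. The largest FoxP3 clusters with GATA1 were 8 peaks at 126086195 to 126134377 on chromosome 8 (scores 72.6 to 103.3) and 7 peaks at 80789013 to 80828080 on chromosome 10 (scores 119.7 to 234.6). A cluster of 4 FoxP3 alone peaks at 126072716 to 126093626 on chromosome 8 (scores 212.9 to 255.4) overlapped the first of these. A cluster of 5 FoxP3 peaks with GATA1 on chromosome 1 (170113129 to 170139980) came next, and the other 7 held 4 peaks each, among them those on chromosomes 15 and X. The FoxP3 alone list held clusters of 5 peaks in these regions of chromosomes 1, 15 and X. Another group of 4 FoxP3 alone peaks lay at 98502214 to 98507667 on chromosome 2 (scores 411.5 to 3100). This group was not particular to FoxP3 alone. A peak with GATA1 at 98502208 to 98503396, with a score of 3100, overlapped it and also overlapped a Pol II peak. The largest Pol II clusters had 12 peaks at 87546109 to 87578062 on chromosome 11, 10 at 23611364 to 23677949 on chromosome 13 and 10 at 69792995 to 69838022 on chromosome 11. They were followed by 9 peaks at 154574926 to 154597352 on chromosome 4 and by 6 clusters of 8, among them the one at 78725442 to 78767071 on chromosome 15.

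The widest FoxP3 peaks included several of the highest-scoring ones. The widest FoxP3 peak with GATA1, 4913 bp at 3000015 to 3004927 on chromosome 11, scored only 88.62 and overlapped the 5256 bp Pol II peak at 2999842 to 3005097. The next were the peaks of the chromosome X and chromosome 15 groups, at 3523 and 2853 bp, and peaks at 32161811 to 32164484 on chromosome 9 (2674 bp) and 3016236 to 3018610 on chromosome 4 (2375 bp). In the FoxP3 alone list the widest were 2569 bp in the chromosome 15 group, 2369 and 2004 bp in the chromosome X group, 1993 bp at 43853892 to 43855884 on chromosome 9, and the 1808 bp peak on chromosome 17 that was absent from the other FoxP3 list. The widest Pol II peak, 6457 bp at 39979489 to 39985945 on chromosome 17, scored 3100 and overlapped no FoxP3 peak. The same held for the 4982 bp Pol II peak at 24618206 to 24623187 on chromosome 1. Wide Pol II peaks of low score at 47711944 to 47717033 (5090 bp, score 70.93) and 47625186 to 47629623 (4438 bp, score 91.65) on chromosome 6 overlapped no FoxP3 peak either.

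By chromosome, Pol II peaks were concentrated on chromosome 11, which held 8.50% (8.10 to 8.92) of them and 4.62% of the span covered by the lists. FoxP3 peaks were less so, with 5.67% (5.21 to 6.17) with GATA1 and 6.29% (5.66 to 6.995) with FoxP3 alone. Chromosome X, with 6.33% of the span, held 2.42% (2.12 to 2.76) of FoxP3 peaks with GATA1, 2.80% (2.38 to 3.29) of those with FoxP3 alone and 1.74% (1.55 to 1.94) of Pol II peaks.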

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

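No value here has a test across samples, and the read depth, on which the length of a list and its scores depend, is unknown. No paired analysis was possible because each group has 1 library. The minimum scores of 150 and above, the removal of peaks of 450 bp or less or scoring 3000 or more, the 1000 highest-scoring peaks and the shifted placement were chosen after seeing the data. Nor were the score of 3000 and the gap of 300 kb that define the joined regions fixed beforehand. The ratio of 1.78 between the lengths of the FoxP3 lists was 1.396 at a minimum score of 150 and reversed to 0.859 at 200, 0.546 at 250 and 0.390 at 300. It moved by less than 1.5 times under the other alternatives run for it, among which leaving out peaks over 5 kb removed none. The share of FoxP3+GATA1 peaks in the FoxP3 alone list was 33.4% with centres within 250 bp, 46.6% at equal list length, 46.3% among the 1000 highest-scoring peaks of each list and 25.9% among peaks over 450 bp. The reverse share was 59.4%, 46.7%, 46.3% and 53.5%, in that order; the last 3 settings also remove possible partners. Pol II overlap with GATA1 was 48.2% when 50% of the shorter peak had to overlap, 41.9% at scores of 100 or more, 47.9% with the Pol II list at the FoxP3 minimum and 45.3% over 450 bp, and with FoxP3 alone 65.8%, 58.0%, 65.8% and 61.9%. With GATA1 it was also 50.8% within 1 kb and 58.4% at equal list length. The difference between the FoxP3 lists was 16.1 points at scores of 100 or more and 9.09 at equal length. At scores of 100 or more, Pol II overlapped 71.0% of shared peaks, 25.9% of peaks only with GATA1 and 36.7% of those only with FoxP3 alone. Over 450 bp, shared peaks had 73.9% and peaks only with GATA1 35.4%; within 1 kb, the single-list shares were 34.7% and 49.2%. Shared peaks had the highest share and peaks only with GATA1 the lowest in these 3 settings. Placement shifted by 1 to 2 Mb gave mean overlaps of 0.294% to 1.15% for the FoxP3 lists. The median distance to a Pol II peak was 13684 bp with GATA1 and 203 bp with FoxP3 alone at scores of 100 or more, and 210 and 0 bp from edge to edge. Clusters of 4 or more peaks numbered 1 with GATA1, 1 with FoxP3 alone and 101 for Pol II with a gap of 5 kb, and 102, 26 and 1058 with a gap of 50 kb. The cause of these changes was not tested beyond the settings' own construction. The alternatives for annotated start sites, gene lists and motifs were not run, since no annotation of the build was used here.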

Other observations

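All tests in this part were chosen after the results had been seen, and intervals cover counting error over the peaks of single libraries. The median distance to the nearest Pol II peak that overlapped no FoxP3 peak differed between classes of FoxP3 sites. Without a Pol II peak of their own, the 3891 sites in the FoxP3+GATA1 list only lay at 86.1 kb (95% interval 79.3 to 92.8), the 642 sites in both FoxP3 lists at 90.2 kb (78.6 to 102.9) and the 1007 sites in the FoxP3 alone list only at 64.2 kb (59.3 to 74.9). Sites in a single FoxP3 list that did overlap Pol II lay at 50.5 kb (45.9 to 55.4) with GATA1 and 40.4 kb (36.7 to 45.6) with FoxP3 alone. Of the latter, 9.80% (8.01 to 11.9) were on chromosome 11, against 9.36% (8.85 to 9.89) of the 12246 Pol II peaks in no FoxP3 list. The corresponding sites with GATA1 had 6.26% (5.27 to 7.42). The 2529 FoxP3+GATA1 sites in all 3 lists had 5.58% (4.75 to 6.54). Among sites without Pol II the shares were 5.30% in both FoxP3 lists, 5.50% with GATA1 only and 5.66% with FoxP3 alone only.

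The chromosome shares of the 2544 Pol II peaks in both FoxP3 lists were compared with those of Pol II peaks of like score. They differed from those of the whole Pol II list, weighted to the same score deciles, by 10.7 percentage points, summed over 21 chromosomes. In 1000 random draws of as many Pol II peaks from these deciles the difference was at most 9.39. This cannot decide whether start sites drawn like the other Pol II peaks were the whole source. The draws treat neighbouring peaks as independent, while the Pol II list held 308 clusters, against a mean of 15.5 for random placement. The range of the draws may therefore be too narrow. Nor was the Pol II list shown to hold start sites only. Positions unrelated to transcription stay open as a source: the 2529 FoxP3+GATA1 sites in all 3 lists lay 62.2 kb (57.5 to 66.0) from a Pol II peak in no FoxP3 list, below every random placement (124.3 kb or more), but sites without Pol II also lay below theirs, those in the FoxP3 alone list only at 64.2 kb. Stacks of reads at fixed positions in every library also stay open, since edges within 3 bp of each other were found in 29.4% of FoxP3 pairs with a Pol II peak against 32.3% without one, in 18.7% against 16.4% of FoxP3+GATA1 and Pol II pairs with and without a FoxP3 alone peak, and in 25.1% against 13.8% of FoxP3 alone and Pol II pairs with and without a FoxP3+GATA1 peak. Neither a preference of FoxP3 among start sites nor non-specific precipitation by the anti-FLAG antibody was tested.

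A candidate source of the groups of peaks scoring 3000 or more on chromosomes 1, 15 and X, and of the single regions that did so in all 3 lists on chromosomes 1, 9 and 11, is DNA of transduced constructs, which the extract lacked by its label. By the labels, DNA of the transduced GATA1 construct alone is excluded as their source, because the FoxP3 alone cells had not received it. This follows from how the 6 regions, these 3 groups among them, were taken, and is not a test. Each scored 3000 or more in every list, FoxP3 alone included. No region scored 3000 or more in both libraries labelled with GATA1 and not in FoxP3 alone. Whether the Pol II cells carried any construct is uncertain, since their description mentions no transduced factor. If they carried none, construct DNA would not account for the Pol II peaks. DNA of the transduced FoxP3 construct stays open for the group on chromosome X, the chromosome that carries the mouse gene: 2 or more such peaks were in 3 of 3 lists, but the gene at that position was not looked up. Neither sequence shared by the constructs nor strong occupancy was tested for any of the 6 regions.

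The FoxP3+GATA1 list was longer and lower in score. Whether its 5840 unshared sites were missed by the FoxP3 alone list through a low score alone stays open: 76.1% (73.2 to 78.8) of its top decile, 61.0% (57.8 to 64.2) of the next and 18.4% (16.0 to 21.1) of the lowest were shared, and no replicate shows how much of a top decile a second library of the same cells would recover. The same is open for the FoxP3 alone list: 95.1% (92.8 to 96.6) of its top decile was shared, but 79.3% (75.5 to 82.6) of the next and 76.9% (73.1 to 80.4) of the one after, and its lowest decile had a higher share (53.3%) than the third from the bottom (41.4%). Whether GATA1 gave more FoxP3 sites cannot be told apart from a difference in depth or background between 2 single libraries: the ratio of list lengths was 0.390 at a common score of 300.

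Peak edges coincided between lists far beyond neighbouring offsets. Of 3178 overlapping FoxP3 pairs, 219 began at the same base, against 5.2 expected from the mean count per offset at 11 to 50 bp. For FoxP3 alone and Pol II the count was 159 of 3443, against 5.25. Narrow Pol II peaks of 450 bp or less overlapped FoxP3+GATA1 peaks in 62.0% (58.5 to 65.5) of cases, against 19.2% (18.3 to 20.1) of the 7743 in the next class of width, over 450 and up to 600 bp, 24.2% (23.1 to 25.4) up to 800 bp and 33.2% (31.7 to 34.7) above. Narrow FoxP3 alone peaks were in the FoxP3+GATA1 list in 78.1% (75.7 to 80.4) of cases, against 53.4% (51.5 to 55.4) in the next class of width, 62.8% (60.0 to 65.5) up to 800 bp and 74.8% (69.8 to 79.3) above. Narrow FoxP3+GATA1 peaks were in the FoxP3 alone list in 35.0% (32.1 to 38.1) of cases, close to the 35.2% of the whole list. The wider classes had 26.8% (25.5 to 28.2), 39.7% (37.9 to 41.6) and 56.3% (53.4 to 59.2). Median scores were also higher in narrow peaks than in the next class of width. They were 152.7 against 95.3 for Pol II, 488.3 against 371.4 for FoxP3 alone and 245.4 against 170.9 with GATA1. Peaks over 800 bp had the highest median in each list, so width and score were not separated here.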
